A study of Homo sapiens and Mus musculus with 61 samples.

How the data were processed

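CAPTURE-ChIP-seq was carried out in K562 cells with biotinylated inactive Cas9, per the labels' protocols. Of the 61 samples of the series, 46 have columns in the tables used here, 42 with a targeting guide and 4 with sgGal4; the other 15 samples, 7 of them human and 8 of mouse cells, were not analysed here. The labels number the replicates but do not say that these came from separate cultures. Every p-value of guide against sgGal4 libraries therefore measures only the spread between libraries, which may be technical. The permutation tests compare guides or windows and Fisher's test compares regions, so their p-values do not measure that spread. Guides were taken to samples by the names in the column headers; for sgHBG-sg2 the label text points to the table of sgHBG, and the column names of the sgHBG-sg2 table were followed.

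Reads were aligned to hg19 with Bowtie 1.0.0 and processed with Picard, per the submitters' processing notes. The peak caller and the method of normalisation are not given in the sources used here. Each table of the authors holds 300 bp regions with columns for M, A, a tag for on-target and off-target regions, each guide library and each of the 4 sgGal4 libraries. The headers state no unit. From the values, the authors deposited log2 levels per library, normalised separately for each table, so all tests were run within a table. M was recomputed as the log2 of the mean linear level of the guide libraries over that of the sgGal4 libraries and differed from the authors' value by at most 1.39e-08; it is not the difference of the mean log2 levels, from which it departs by up to 3.46. All log2 ratios given here are this recomputed value, and n counts the guide libraries.

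Within a column the log2 levels form a straight line in the log2 of whole numbers. The start of the line was taken as its lowest value and the slope from the next value. With these, 100% of values in every column came out whole within 0.01, or within 0.01% of the level where that is larger. The slope differed between columns, such as 0.596 for sgGal4 replicate 3 in the sgHS3-sg2 table and 1.38 for sgGal4 replicate 1 in that of sgHS5. A log2 ratio given here is therefore not a log2 ratio of reads. The whole number less 1 was taken as the read number, which the headers do not state. Of 4588 regions present in 2 or more tables, 0 differed in the recovered reads of any sgGal4 library. The sum over the listed regions is not the depth of a library. sgGal4 replicates 1 and 2 held 41128 to 169968 reads in the regions of a table and replicates 3 and 4 held 6499 to 18647, with 25.8% to 40.7% of regions at 0 reads. A region at 0 reads was placed at a log2 level of up to 3.68 in those shallow libraries, which lowers ratios to the sgGal4 mean. Intervals for shares of reads are exact Clopper-Pearson intervals at 95% and cover counting error only.

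The plan written before the data were examined named a test for counts for tables with a column per library. The deposited values are log2 levels, not counts, so limma 3.58.1 in R 4.3.3 was used on the log2 values. The fit compared guide against sgGal4 with empirical Bayes variances without a trend and Benjamini-Hochberg adjustment within a table. A region counted as enriched with a log2 ratio of at least 1 and a limma p of at most 1e-05. The plan took this p from the tables, which hold none, so limma's was used. On-target calls used an adjusted p below 0.05. In tables with 1 guide library, that library was taken to vary like the sgGal4 libraries. The fit was tested on simulated data with the spread of each table and 200 changed regions. The simulated noise was normal, with the variances of the fit itself and no floor at 0 reads, which favours the fit. Of regions raised by 4 on the log2 scale, between 0.5% (sgHS2-sg2, with 1 guide library) and 100% (sgHBB-sg2) passed the p limit, with 87.5% for sgHBG and 15% for sgHS5. Of those raised by 2, at most 10.5% passed, so smaller changes were mostly not detectable at the p limit. False calls at the p limit numbered at most 1 in each simulated table. These rates describe the simulation and can be too favourable for the real regions. The target of sgHBB-sg2, with a limma log2 difference of 6.02, had a limma p of 6.83e-05 and did not pass the p limit.

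The on-target region was the region with the highest ratio whose centre lay within 1.5 kb of a nominal site position. The cluster was taken as the interval from beyond 3'HS1 to beyond HS5. Genes and introns came from the protein-coding transcripts of GENCODE 44 lifted to GRCh37, which has the coordinates of hg19; genes without a symbol were left out, and the nearest gene is the one with the nearest transcription start. Region starts are given counted from 1; the starts in the files were taken as counted from 0, since end less start is 300. Named regions followed a rule fixed beforehand. They were the on-target regions, the 3 highest enriched regions outside the cluster for each guide, the 10 enriched in the most tables with ties ordered by mean log2 ratio, and members of lists of alpha-globin, beta-globin, erythroid regulator, architectural and cohesin genes, K562 amplified intervals, and mitochondrial and unplaced contigs. All 5 beta-globin genes of the cluster were nearest to regions, 32 in all, of which 14 had a log2 ratio of at least 1, 7 passed the p limit and 10 had an adjusted p below 0.05.

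Overlap of guides was tested by an exact permutation of the matching between first and second guides, overlap with the pool by an exact permutation of the guides, and other cluster sites by permuting the windows within tables. Regions were shared if they overlapped by at least 1 bp. Shared sgGal4 libraries were addressed with 20 simulations of unchanged guides and by dividing the sgGal4 libraries, replicates 1 and 3 for some tables and 2 and 4 for the others. Alternatives covered the target window, the p limit, a minimum of 20 reads, the amplified intervals, re-centring, recovered reads with a pseudocount of 1 or 5, the replicate number as a block and leaving out each library. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.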

Results

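CAPTURE-ChIP-seq recovers the DNA bound by a catalytically inactive Cas9 that carries a biotin tag and is steered by a single guide RNA (sgRNA). The tagged protein is pulled down on streptavidin beads and the DNA that comes with it is sequenced. The libraries analysed here come from K562, a human leukaemia line that expresses embryonic and fetal globin genes. Guides were directed at the beta-globin cluster on chromosome 11, and every guide was compared with a guide against yeast Gal4, which has no intended target in the human genome. There were 42 libraries with a targeting guide and 4 with sgGal4. There were 9 first guides. Of these, 5 were aimed at HS1 to HS5, the DNase I hypersensitive sites of the locus control region that enhances the globin genes. The others were aimed at the promoters of HBB (adult beta-globin) and of HBG1 and HBG2 (the paired fetal gamma-globin genes), at a site upstream of HBD (delta-globin) named HBD-1kb, and at 3'HS1, a hypersensitive site at the other end of the cluster. A further 7 guides, labelled sg2, were aimed a second time at HS1 to HS5, HBB and HBG, and 1 pool, sgHS1-5, held guides for the 5 hypersensitive sites. The number of libraries per guide was 1 for sgHBB, sgHS2-sg2 and sgHS3-sg2, 3 for sgHS3 and sgHS5, 4 for sgHBG, 5 for sgHS2, 6 for the pool and 2 for the others. Each of the 17 tables listed between 4217 and 16890 regions of 300 bp, in hg19. Read numbers worked out from the values came to between 7127 and 432553 per guide library within the regions of its table, and to between 6499 and 169968 for the sgGal4 libraries.

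The first question was whether each guide brought Cas9 to its intended site. Among the first guides to the locus control region, the on-target region lay far above sgGal4 at all 5 sites and had the highest log2 ratio of its table. At HS1 (chromosome 11, 5296853 to 5297152) the log2 ratio was 5.64 (SD of the guide libraries 2.34, n = 2), with a limma adjusted p of 0.0274. At HS2 (5301954 to 5302253), the strongest classical enhancer of the region, it was 7.67 (SD 1.58, n = 5), with an adjusted p of 7.79e-05. At HS3 (5305767 to 5306066) it was 8.86 (SD 1.58, n = 3), with an adjusted p of 0.00251. At HS4 (5309425 to 5309724) the ratio was 9.28 (SD 1.51, n = 2) and at HS5 (5312418 to 5312717), which binds CTCF, 7.62 (SD 1.71, n = 3), but limma's adjusted p was 0.0568 and 0.0582. These differences did not pass 0.05 in this fit. On recovered reads with a pseudocount of 1 both did, with limma adjusted p of 5.32e-05 and 0.00317. The annotation places all 5 regions in an intron of long HBE1 transcript models. The sgHS1 call did not hold without any of the sgGal4 libraries in turn, with adjusted p of 0.0501, 0.0554, 0.078 and 0.0799 for replicates 1 to 4. For sgHS5 limma's adjusted p fell to 0.0108 without its replicate 1 and rose to 0.315 and 0.278 without its replicates 2 and 3. With 1 library left, the ratio of sgHS4 was 7.85 without its replicate 1 and 9.99 without its replicate 2. By reads the order was the reverse. The HS4 region held 5.62% of the reads in the listed regions in replicate 1 and 18.6% in replicate 2.

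**Figure D1:**
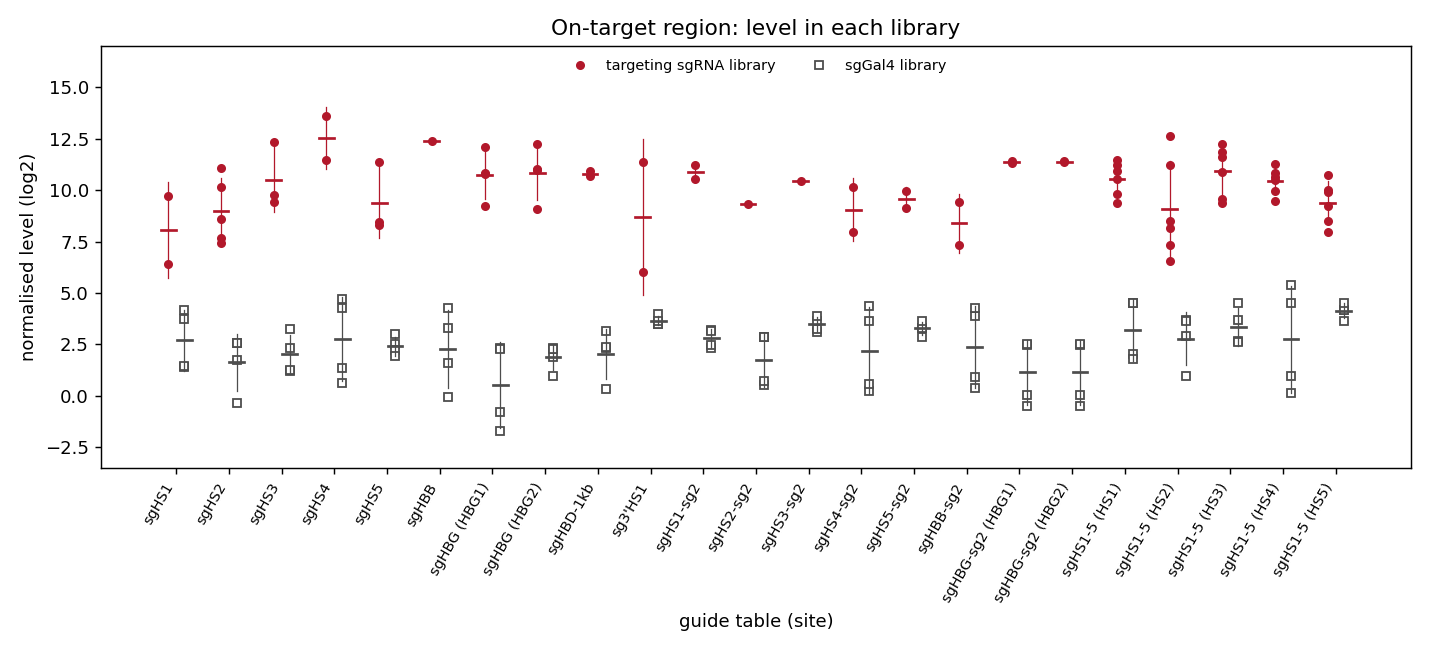
Normalised log2 level of the on-target region in each library (y axis) for each guide table, with the site in brackets where a table has several (x axis); filled points are libraries of the targeting guide, open squares the sgGal4 libraries, short bars the means and thin lines 1 SD. Every library of a targeting guide lies above every sgGal4 library of its table; the lowest ratio to the sgGal4 mean is the 2.35 of sg3'HS1 replicate 1.

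At the genes, sgHBB raised the HBB promoter region (5248255 to 5248554, over the first exon and 23 bp from the transcription start) to a log2 ratio of 9.35 in its single library, with an adjusted p of 0.00841 that takes this library to vary like the sgGal4 libraries. sgHBG raised both gamma-globin promoters, HBG1 (5271083 to 5271382) by 9.62 (SD 1.16, n = 4; limma adjusted p = 0.000177) and HBG2 (5276001 to 5276300) by 9.25 (SD 1.31, n = 4; limma adjusted p = 2.21e-05), and these were ranks 1 and 2 among 6808 regions. The HBD-1kb region (5256832 to 5257131), 381 bp from the nearest annotated HBD start, reached 8.45 (SD 0.15, n = 2) with a limma adjusted p of 0.0086; with only replicate 2 or only replicate 1 of the guide it was 8.34 and 8.56, and the adjusted p became 0.102 and 0.0623. The 3'HS1 region (5226142 to 5226441, intergenic) had a ratio of 6.74, but its libraries lay far apart (SD 3.79, n = 2) and limma's adjusted p was 0.0856. Replicate 1 of sg3'HS1 held 64 of its 147774 reads there, 0.0433% (95% Clopper-Pearson interval 0.0334 to 0.0553), and replicate 2 held 1288 of 29397, 4.38% (4.15 to 4.62). The region ranked 1 with replicate 2 alone and 627 with replicate 1 alone, and sg3'HS1 was the only single guide with no target region at rank 1 of its table.

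The second guides reached the same elements. Their log2 ratios were 8.07 at HS1 (SD 0.48, n = 2), 7.19 at HS2 (n = 1), 6.93 at HS3 (n = 1), 6.28 at HS4 (SD 1.53, n = 2), 6.30 at HS5 (SD 0.58, n = 2), 5.50 at HBB (SD 1.45, n = 2), and 9.65 and 9.67 at HBG1 and HBG2 (SD 0.09 and 0.05, n = 2). At both of these, and at HBG1 for sgHBG, the 4 sgGal4 libraries held 0 reads, so the size of these ratios is set by the value given to 0 reads. The ratio of sgHBB-sg2 at HBB also depends on the scale, and was 9.01 on recovered reads with a pseudocount of 1. All 8 of these regions had a limma adjusted p below 0.05, from 0.000424 to 0.0288, and each guide's target ranked first in its table. For sgHS2-sg2 and sgHS3-sg2, with 1 library, this p rests on the spread among the sgGal4 libraries, and replicated guide libraries spread more at some targets (sgHS5 SD 1.71 against 0.46 in sgGal4). For sgHBG-sg2, HBG2 ranked 1 and HBG1 ranked 2. The regions of the paired guides began between 16 and 549 bp apart. The second guide was lower by value at HS2, HS3, HS4, HS5 and HBB and higher at HS1, HBG1 and HBG2; the tables were normalised separately, so these differences were not tested. The order is not stable: on recovered reads it turned at HS1 (9.13 for the first and 8.55 for the second guide with a pseudocount of 1) and HS5 (5.97 and 6.83), and with a pseudocount of 5 also at HBG1 (10.57 and 10.53). The adjusted p rose above 0.05 without replicate 1 of the guide for sgHS1-sg2 (0.0641), sgHS4-sg2 (0.0728), sgHS5-sg2 (0.0805) and sgHBB-sg2 (0.0692), and for sgHS2-sg2 without any of the sgGal4 libraries (0.0589 to 0.0794). In the 3 single-library tables the on-target region held 6.06% (5.90 to 6.22) of the reads of sgHBB, 0.598% (0.553 to 0.647) of those of sgHS2-sg2 and 2.15% (2.04 to 2.26) of those of sgHS3-sg2; the 95% Clopper-Pearson intervals cover counting error only.

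The pool of guides for the 5 hypersensitive sites raised all of them. The log2 ratios over its 6 libraries were 6.98 at HS1 (SD 0.82), 7.53 at HS2 (SD 2.36), 7.69 at HS3 (SD 1.21), 6.48 at HS4 (SD 0.64) and 5.50 at HS5 (SD 1.03), with limma adjusted p of 7.31e-05, 0.0387, 7.31e-05, 0.00109 and 0.000328, and ranks of 3, 2, 1, 4 and 6 among 16890 regions. HS2 was the least even target. It held 176, 359, 9 and 16 reads in replicates 1 to 4, and 3058 and 5342 in replicates 5 and 6, or between 0.043% and 5.28% of the reads in the listed regions. HS1 varied between 0.421% and 1.91%. The HS2 call did not hold without pool replicate 1 (adjusted p = 0.0934), 2 (0.09), 4 (0.0557) or 5 (0.112), nor without sgGal4 replicate 1 (0.205) or 2 (0.102).

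**Figure D2:**
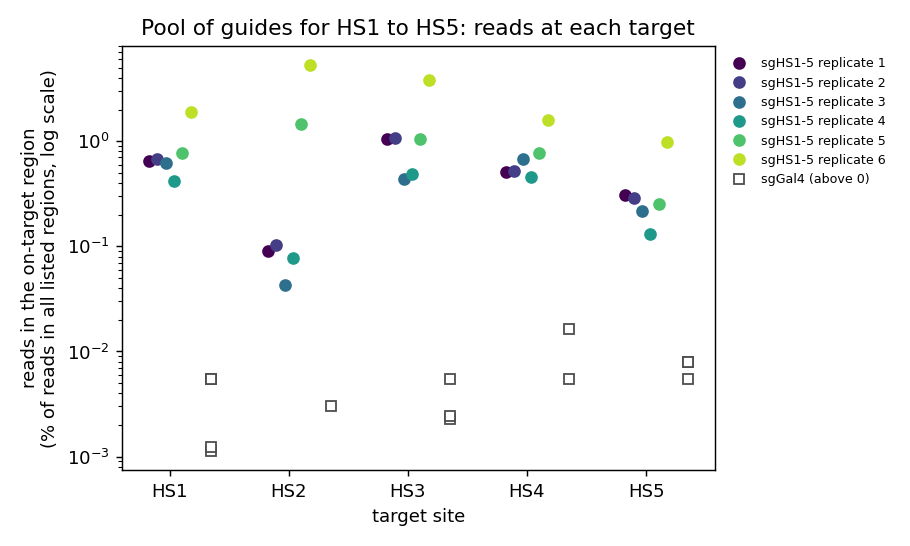
Reads in the on-target region of each hypersensitive site (x axis) as a percent of the reads in all listed regions of the pool table, on a log scale (y axis); filled points are the 6 pool libraries and open squares the sgGal4 libraries with any read there. All 6 pool libraries lie above the sgGal4 libraries at every site, and HS2 spans from 0.043% to 5.28%.

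The next question was how many other places in the genome each guide enriched. Outside the beta-globin cluster, 27 regions in 7 tables had a log2 ratio of at least 1 and a limma p of at most 1e-05: 10 for sgHBG, 9 for sgHS3, 3 for sgHBD-1kb, 2 for sg3'HS1 and 1 each for sgHS4, sgHBB and the pool. For sgHS3 the highest was an intergenic region on chromosome 6 (142942824 to 142943123) whose nearest gene is HIVEP2, a zinc-finger transcription factor gene (log2 ratio 7.38, SD 1.38, n = 3). It was followed by a region in an intron of the glutamate receptor gene GRM8 on chromosome 7 (126342515 to 126342814; 6.41, SD 1.31) and a region near FAM83C on chromosome 20 (33887600 to 33887899; 6.41, SD 1.41). For sgHBG they were a region 12178 bp from the start of SYF2, a splicing factor gene, on chromosome 1 (25546650 to 25546949; 7.65, SD 1.02, n = 4), an intron of the Rag GTPase gene RRAGD on chromosome 6 (90094921 to 90095220; limma log2 difference 5.99, SD 1.42) and a region near PCBD1 on chromosome 10 (72667238 to 72667537; 5.69, SD 1.28). For sgHBD-1kb they were an exon of the leptin receptor gene LEPR on chromosome 1 (66103044 to 66103343; 6.39, SD 0.20, n = 2), an intron of CD247, which encodes the T-cell receptor zeta chain (167486790 to 167487089; 4.55, SD 0.08), and an intron of AHDC1 (27894908 to 27895207; 4.26, SD 0.04).

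The remaining guides with such regions had few in this fit. sgHS4 had a region 870 bp from the start of RNF44 on chromosome 5 (175965124 to 175965423; log2 ratio 8.12, SD 1.49, n = 2). sgHBB had an exon of MGAT5, which encodes an N-glycan branching enzyme, on chromosome 2 (135208382 to 135208681; 6.51, n = 1). The pool had a region near DPH6 on chromosome 15 (35840073 to 35840372; 3.92, SD 0.32, n = 6). sg3'HS1 had an exon of the deubiquitinase gene USP20 on chromosome 9 (132625397 to 132625696; 7.28, SD 0.68, n = 2), which ranked above the 3'HS1 site itself, and a region near PLEKHF2 on chromosome 8 (96108381 to 96108680; 5.19, SD 0.34). No region outside the cluster passed in more than 1 table, so the 10 regions ranked by mean log2 ratio over tables are the ones already given for sgHS4, sgHBG, sgHS3, sg3'HS1, sgHBB and sgHBD-1kb, from RNF44 down to PCBD1. In the other 10 tables limma passed 0 regions at this limit, whereas between 142 (sgHBB-sg2) and 1136 (sgHS5), and 23 for sgHS1, had a log2 ratio of at least 1 and an unadjusted p below 0.05. The same test on recovered reads passed 2 for sgHS2, 1 each for sgHS5 and sgHS1-sg2, and 0 in the other 7. Among the tables with passing regions it gave more, with 52 for sgHS3, 63 for sgHBG, 25 for sgHS4, 28 for sg3'HS1 and 8 for sgHBD-1kb. With an adjusted p below 0.05 in place of the p limit, 2364 regions passed over all tables, all outside the cluster. Of these, 938 were for sgHBD-1kb, 500 for sgHS3, 334 for sgHBG and 218 for sgHBB, with 0 for sgHS2 and sgHS5. Many regions were also lower than in sgGal4, up to 3262 with a log2 ratio of -1 or below for sgHBB, where the median of all regions outside the cluster was -1.53. With the same adjusted p limit, regions at -1 or below outnumbered those at 1 or above in most tables. There were 1862 against 938 for sgHBD-1kb, 870 against 334 for sgHBG and 759 against 500 for sgHS3. More were raised than lowered for sgHS4 (1 against 0), sg3'HS1 (2 against 0) and the pool (4 against 0). A region passing this limit is therefore not by itself a site of the guide. The counts at the p limit changed when single libraries were left out, which also leaves fewer libraries for the test. The regions need not be raised in 1 library only. For sgHS3, a region in an intron of MAP3K5 held 123, 71 and 97 reads, against 4, 6, 1 and 0 in sgGal4. The 9 of sgHS3 became 0 when any of its 3 libraries was left out and 5 without sgGal4 replicate 4. The 10 of sgHBG became 3 without its replicate 1, 3 or 4 and 4 without sgGal4 replicate 1. The 3 of sgHBD-1kb became 0 without either of its libraries or without sgGal4 replicate 1 or 4, and 1 without replicate 3. The 2 of sg3'HS1 became 0 without either of its libraries and 1 when any sgGal4 library was left out. The region of sgHS4 was lost without its replicate 1, that of sgHBB without sgGal4 replicate 3 or 4 (2 and 6 regions passed without replicates 1 and 2), and the pool had 2 and 3 without its replicates 3 and 4.

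**Figure D3:**
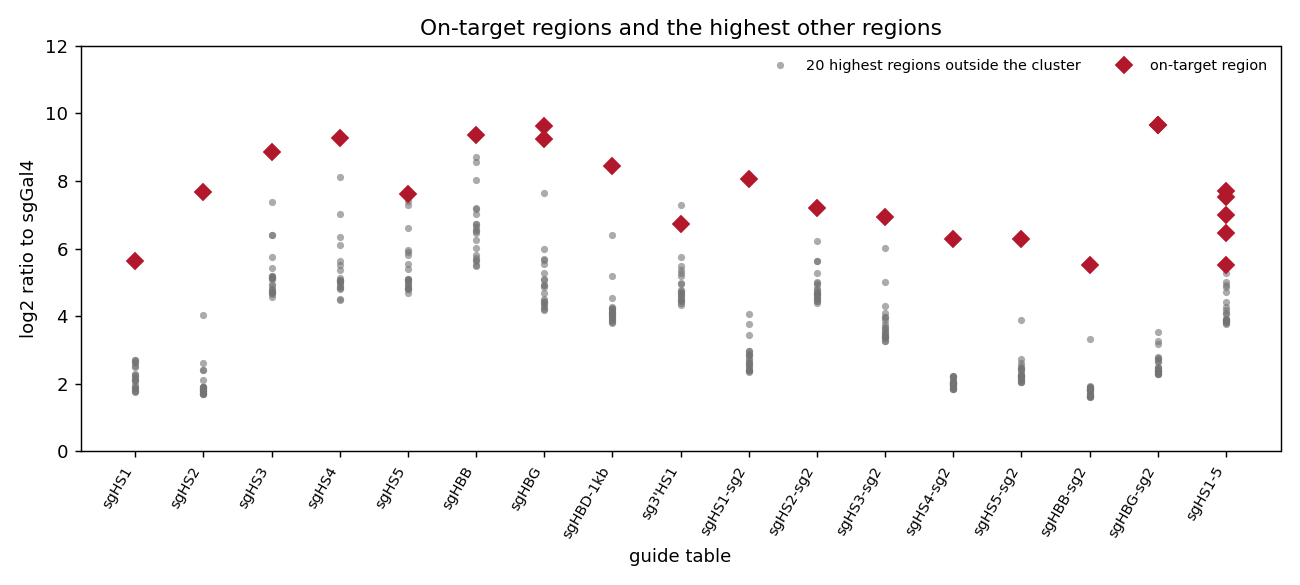
Log2 ratio to sgGal4 (y axis) of the on-target regions (diamonds) and of the 20 regions outside the beta-globin cluster with the highest log2 ratio (grey points) for each guide table (x axis). The highest other region reaches 8.70 for sgHBB and 2.24 for sgHS4-sg2, and it lies above the target for sg3'HS1 and above the HS5 target of the pool (5.53 against 5.50).

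The distance between the target and the rest of the genome differed widely between guides. The highest log2 ratio outside the cluster was 8.70 for sgHBB, in an intron of ARVCF on chromosome 22 (19975284 to 19975583), 7.41 for sgHS5, in an intron of GPR157 on chromosome 1 (9170911 to 9171210), and 6.21 for sgHS2-sg2, near UBE2N on chromosome 12 (93847825 to 93848124). It was 4.03 for sgHS2 and between 2.24 and 4.06 for the second guides to HS1, HS4, HS5, HBB and HBG, and 2.71 for sgHS1. These regions were chosen after their values were seen. For sgHS2 the highest was an intron of PGK1, a glycolysis gene, on the X chromosome, where 1 library (replicate 2) held 423 reads and the others at most 6, the SD was 3.75 and limma's adjusted p was 0.419. With no p limit, a region at PGK1 (77359346 to 77359808) had a log2 ratio of at least 1 in 8 tables, with a mean of 2.15.

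The authors' deposited tables tag 34 regions outside the cluster as off-target, in 11 of the 17 tables. The authors' deposited table of sgHS4 has 8 of them, with log2 ratios from 1.86 to 7.03; the highest lies in an intron of ABCC11 on chromosome 16 (48245857 to 48246156), and none had a limma adjusted p below 0.05. In the authors' deposited tables the tagged region with the highest ratio for sgHBD-1kb is the LEPR exon, at 6.39, and for sgHBG an intron of MYRIP on chromosome 3 (4.17; limma adjusted p = 0.0211). The 5 tagged regions of sgHS3 in the authors' deposited table run from 0.58 to 4.79, the highest in an intron of TMC4 on chromosome 19. Of the 34 regions tagged in the authors' deposited tables, 1, the LEPR exon, passed the p limit and 9 had a log2 ratio of at least 1 with a limma adjusted p below 0.05. Regions without a tag exceeded the highest tagged one in 10 of the 11 tables in the authors' deposited set, among them 14 regions for sgHS3, 19 for sgHBG and 412 for sgHBB.

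The gene groups fixed before the data were examined were tested in every table that lists a region near them. Of the 5 alpha-globin genes, 3 were nearest to a region within 10000 bp of a start, and none of their 13 regions over all tables passed either limit by limma, nor did any adjusted over the list alone. Of these, 3 had a log2 ratio of at least 1. The highest was 1.22 near HBQ1 for sgHS5. Of 15 erythroid regulator genes, 13 had such regions, 85 in all, and none passed the p limit, while 5 regions had an adjusted p below 0.05 by limma, or 2 adjusted over the list alone. The 5 were near LMO2, a LIM-domain partner of TAL1 (log2 ratio 3.69 for sgHBD-1kb), KLF1, an activator of HBB (3.31 for sgHBB), LDB1 (2.11 for sgHS3), LYL1 (1.80 for sgHBD-1kb) and TAL1. Regions near GATA2, GFI1B and NFE2 stayed below a log2 ratio of 1 in every table. Of 7 architectural and cohesin genes, 6 had 26 regions, of which none passed the p limit by limma and 1, near CTCF, had an adjusted p below 0.05, or 0 adjusted over the list alone. The highest near CTCF was 2.03 for sgHS4-sg2. The 2 amplified intervals of K562, around BCR on chromosome 22 and ABL1 on chromosome 9, held 260 regions over all tables, of which 20 had a log2 ratio of at least 1, 4 of them with a limma adjusted p below 0.05 (2 adjusted over the list alone), and 0 passed the p limit. No listed region lay on the mitochondrial genome or an unplaced contig.

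Guides for the same target were compared to ask whether they share regions elsewhere that guides for different targets do not. No second guide had a region outside the cluster that passed, so none was shared with a first guide. The mean Jaccard index was 0 for the 7 same-target pairs and 0 for the 42 other pairs (exact permutation p = 1 over 5040 matchings, one-sided). At this limit the comparison carries no information. The log2 ratios over all regions in both tables, counted without a limit, correlated by 0.659 on average in same-target pairs and by 0.661 in the others (exact permutation p = 0.587, one-sided; regions are not independent replicates). The lowest same-target correlation was 0.383 for HBB and the highest 0.813 for HS4. Unchanged guides simulated against the same sgGal4 libraries gave 0.0303, with a covariance of 0.00738 against the 0.737 observed; with the sgGal4 libraries divided between the tables the observed correlation was 0.559 and the covariance 0.674. Regions with a log2 ratio of at least 1 in both tables numbered 227 in the same-target pairs, where independent lists would give 20.6, and 1816 in the other pairs, where they would give 202.

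The pool was compared with the single first guides for its 5 sites in the same way. Whether the pool held these same guides is in doubt for HS4 and, by a smaller distance, for HS5. At HS4 its region began at 5309265, nearer to that of sgHS4-sg2 (5309258) than to that of sgHS4 (5309425). At HS5 it began at 5312435, nearer to that of sgHS5-sg2 (5312434) than to that of sgHS5 (5312418). None of the regions passing for a single first guide was among those of the pool, and only sgHS3 and sgHS4 of the 5 hypersensitive site guides had any. The exact permutation p was 1 (15 splits, one-sided) and could not fall below 0.05. An alternative without the p limit, added after the data were seen, found 32.4% of the regions of the 5 hypersensitive site guides with a log2 ratio of at least 1 in the pool, on average, against 9.68% for sgHBB, sgHBG, sgHBD-1kb and sg3'HS1 (exact permutation p = 0.00794, one-sided, the smallest that 126 splits allow). The share was 54.9% for sgHS1, 46.3% for sgHS3, 24.2% for sgHS2 and 19.4% for sgHS5, 230 of 1353 regions for sgHS4, and between 3.27% and 13.1% for the other guides. These shares count regions that the pool table does not list, such as all but 92 of the 947 of sgHBB. Among regions listed in both tables, a further alternative added later, the shares were 63.0% and 43.7% (exact permutation p = 0.0238, one-sided), and that of sgHS5 (45.6%) lay below those of sgHBD-1kb (48.7%) and sg3'HS1 (50.1%). The regions near HIVEP2, in GRM8 and near FAM83C that were highest for sgHS3 also led the pool outside the cluster, with log2 ratios of 5.53, 5.29 and 5.00, of which the first had a limma adjusted p of 0.0346 and the others 0.0629. With an adjusted p limit the difference was -12.4 percentage points (exact permutation p = 0.714, 35 splits), the pool having 4 such regions; 1 of the 2 regions of sg3'HS1 makes this value, the other guides outside the hypersensitive sites sharing 0. Simulated unchanged libraries shared 0.823% and 0.747%. With the sgGal4 libraries divided between the tables the shares were 25.1% and 8.58%, or 24.5% and 8.35% the other way round. Independent lists would share 384 regions with the pool in the 5 tables and 179 in the other 4, where 1777 and 892 were shared. An excess over independent lists was thus not particular to the hypersensitive site guides.

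Within the beta-globin cluster, the tables list few regions apart from the targets. The 16 single-guide tables held 5 windows at other elements, in 3 tables, with log2 ratios between -0.05 and 1.88 and a median of 0.52. The highest were HS2 (1.88, limma adjusted p = 0.244) and HBD-1kb (1.54, limma adjusted p = 0.418) in the sgHS4 table, and the 3'HS1 window was at -0.05 there and at 0.52 for sgHS4-sg2. Windows were averaged within each of those 3 tables and then over the tables. The target windows came to 8.33 and the others to 0.67, a difference of 7.66 (permutation p = 0.0423, 100000 resamples, one-sided). The 24 arrangements of these windows allow no p below 0.0417, and the targets were already the highest regions of these tables, so the test adds nothing to their ranks. With a window of 3 kb the difference was 8.56 (permutation p = 1e-05), again for targets already known to rank high. Signal at elements with no listed region was not analysed here.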

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

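The counts of splits were chosen as tests after the enriched regions had been seen. Samples far from the rest of their group were looked for at the on-target regions, in the 31 groups of 4 to 6 libraries. These groups are not independent, since the same sgGal4 libraries recur at every target and the sgHBG and pool libraries at several. None lay beyond Dixon's 95% limit, where chance alone would give about 1.55. The test does not cover guides with fewer libraries, such as the pair of sg3'HS1 libraries, and it does not detect libraries that fall into 2 sets, as the pool libraries do at HS2.

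Other splits of the same libraries were used to ask whether chance could give as many enriched regions outside the cluster. For sgHBG, with 10 regions, 1 of 35 splits gave as many, the real one, and the highest of the others was 0; for sgHS3, with 9 regions, it was likewise 1 of 35 and 0. This is under 0.05 of the splits for both and is the smallest share that 35 splits allow. It argues against a random division of the libraries. The test was chosen after the regions were seen and was not corrected for the number of tables, so chance is not excluded. For the pool, with 1 region, 3 of the 100 splits drawn gave as many. This is under 0.05 of the splits, but it cannot exclude chance for the pool, since the highest other split gave 29 regions. That split set pool replicates 3 to 6 with sgGal4 replicates 3 and 4 against replicates 1 and 2 of both groups, which points to a structure of these libraries other than the guide. Depth alone does not describe it, since pool replicates 5 and 6 held 210293 and 101221 reads in the regions and replicates 3 and 4 held 20918 and 20447. The level given to 0 reads did separate the sets. It lay between 2.13 and 3.70 on the log2 scale in pool replicates 3 to 6 and sgGal4 replicates 3 and 4. In replicates 1 and 2 of both groups it lay between 0 and 0.95. Whether this scaling gave the 29 regions was not tested, and no fit within such sets of libraries was made. For sgHS2 and sgHS5, with 0 regions each, every one of the 100 and 35 splits gives as many by construction, so the count says nothing about chance; the highest other splits gave 1 and 2.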

How the results depend on the processing

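Alternatives were planned before the data were examined, except the limma variance trend, the adjusted p limit, the lists with no p limit for overlaps (all regions, or those listed in both tables), the divided sgGal4 libraries, and recovered reads for ranks and counts, which were added after seeing the data. DESeq2 and edgeR were not run, since the values are not counts. No on-target ratio changed sign. Windows of 0.5 and 3 kb, a minimum of 20 reads, re-centring and leaving out the amplified intervals changed no call and no count by over 1.5 times; the cause of the changes below was not tested. With a pseudocount of 1 and 5 on recovered reads, sgHS4 (12.20 and 11.26), sgHS5 (5.97 and 5.93) and sg3'HS1 (5.70 and 5.50) passed the adjusted p of 0.05, and the pool at HS2 did not with 5 (8.40). Ratios that kept their call moved as well, such as sgHBB-sg2 from 5.50 to 9.01 and 7.77, sgHS1 from 5.64 to 9.13 and 8.02, sgHBB from 9.35 to 12.80 and 11.19, sgHBG at HBG1 from 9.62 to 12.87 and 10.57, and sgHBG-sg2 at HBG1 from 9.65 to 12.99 and 10.53. With a variance trend sgHS4 (9.28), sgHS5 (7.62) and sg3'HS1 (6.74) passed. Ranked by limma p, the target fell to 3 for sgHS4, 17 for sgHBB, 150 for sg3'HS1, 4 for sgHS2-sg2, and was 2 and 1 for sgHBG at HBG1 and HBG2, and 2, 9 and 3 for the pool at HS1, HS2 and HS5. On recovered reads the ranks were 9 (sgHS5), 3 (sgHBG at HBG2), 30 (sg3'HS1), 2 (sgHS3-sg2 and sgHS5-sg2), and 4, 3 and 24 for the pool at HS1, HS4 and HS5.

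The number of enriched regions moved most. In the order sgHS1, sgHS2, sgHS3, sgHS4, sgHS5, sgHBB, sgHBG, sgHBD-1kb, sg3'HS1, second guides to HS1, HS2, HS3, HS4, HS5, HBB and HBG, and pool, no p limit gave 82, 281, 1897, 1353, 2855, 947, 934, 2988, 3277, 1548, 2329, 601, 394, 771, 202, 746 and 3565. An adjusted p below 0.05 gave 1 for sgHS1, 500, 218, 334 and 938 for sgHS3, sgHBB, sgHBG and sgHBD-1kb, 48, 96, 70, 32, 35, 26 and 59 for the second guides and 4 for the pool. The variance trend gave 1 (sgHS2), 23 (sgHS3), 51 (sgHS4), 11 (sgHS5), 20 (sgHBB), 42 (sgHBG), 30 (sgHBD-1kb), 109 (sg3'HS1), 2 (sgHS1-sg2), 7 (sgHS2-sg2), 1 (sgHS3-sg2), 1 (sgHBB-sg2) and 14 (pool). Recovered reads gave 2 (sgHS2), 52 (sgHS3), 25 (sgHS4), 1 (sgHS5), 3 (sgHBB), 63 (sgHBG), 8 (sgHBD-1kb), 28 (sg3'HS1), 1 (sgHS1-sg2) and 4 (pool). A log2 ratio of at least 2 with p at most 1e-10 left 0 in every table. Without the p limit the pool shared 22.7 percentage points more with the first guides for its 5 sites, not all of which it need have held (exact permutation p = 0.00794) and 20.6 at a log2 ratio of at least 2 (p = 0.0397); at 3 it was 8.08 (p = 0.0714). Among regions listed in both tables, added later still, it was 19.3 (exact permutation p = 0.0238) and, at 2, 30.6 (p = 0.0397). At a log2 ratio of 2, sgHS3 shared 209 of 504 regions and sgHS1 7 of 13, but sgHS2 0 of 5, sgHS4 5 of 155 and sgHS5 41 of 496; at 3, sgHS3 shared 41 of 135 and the other single guides at most 1.59%. With an adjusted p the difference was -12.4 (exact permutation p = 0.714), made by 1 region of sg3'HS1. With each of the 7 targets left out, the correlation of guides with the same target did not differ from that of others beyond chance (exact permutation p between 0.251 and 0.786); it was higher by value only without HS2 (0.680 against 0.675).

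Same-numbered guide and sgGal4 libraries did not deviate together from their group means. In the tables with 3 or more such numbers the correlations lay between -0.06 and 0.13. This does not exclude a shared batch, since depth followed the number in the pool table. Replicates 1 to 4 held 196951, 348211, 20918 and 20447 reads in the pool and 88378, 163456, 18353 and 18413 in sgGal4. With a replicate block the call ended for sgHS1 (6.62) and the pool at HS2 (4.84) and was gained for sgHS4 (11.53) and sg3'HS1 (4.96). The replicate block gave 3 regions for sgHS3, 12 for sgHS4, 6 for sgHBG, 1568 for sgHBD-1kb, 1 for sg3'HS1, 447, 91, 165, 1 and 1 for the second guides to HS1, HS4, HS5, HBB and HBG, and 2 for the pool; with 2 guide libraries it leaves 1 residual degree of freedom. The overlap and cluster tests were at their limits in the block and without it (p of 1 and 0.0423), so they show no stability.

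Leaving out each library in turn gave on-target ratios of 3.19 to 6.50 (sgHS1), 7.85 to 9.99 (sgHS4), 5.92 to 8.06 (sgHS5), 8.13 to 8.87 (sgHBD-1kb), 2.35 to 7.70 (sg3'HS1), 7.69 to 8.38 (sgHS1-sg2), 6.90 to 7.55 (sgHS2-sg2), 4.82 to 7.09 (sgHS4-sg2), 5.83 to 6.65 (sgHS5-sg2), 4.14 to 6.19 (sgHBB-sg2) and 6.26 to 7.78 (pool at HS2). With 1 guide library left, it was assumed to vary like the others. Ranks ran from 1 to 3 (sgHS5), 1 to 627 (sg3'HS1), 1 to 2 (sgHBG-sg2 at both promoters), and 2 to 4, 1 to 4, 1 to 2, 3 to 4 and 5 to 8 for the pool at HS1 to HS5. Counts of enriched regions ran from 0 to 7 (sgHS3), 0 to 1 (sgHS4), 0 to 6 (sgHBB), 3 to 13 (sgHBG), 0 to 3 (sgHBD-1kb), 0 to 1 (sg3'HS1) and 1 to 3 (pool). Depth limits the shallow libraries: 25.8% to 40.7% of regions had 0 reads in sgGal4 replicates 3 and 4, and 41.5% in sgHS2 replicate 2.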

Other observations

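The tests on high-ratio regions, on the pool libraries and of guide matches at promoters were chosen after their results, or parts of them, had been seen, including the limits of 7 bases and of a log2 ratio of 3. Only the tests of shallow sgGal4 libraries and of GC content were set out before. Promoters were common among the moderately raised regions of several second guides, and to a lesser extent of some first guides, such as sgHS3 (39.3% against 21.4% of the other regions) and sg3'HS1 (52.2% against 37.9%). Of the regions with a log2 ratio of at least 1, 73.4% lay within 1000 bp of a transcription start for sgHS1-sg2, 61.9% for sgHS4-sg2, 75.7% for sgHS5-sg2, 56.4% for sgHBB-sg2 and 70.5% for sgHBG-sg2, against 33.8%, 25.6%, 29.6%, 23.6% and 28.7% of the other regions. For sgHS2-sg2 the shares were 19.6% and 18.1%, and for sgHS3-sg2 32.9% and 27.3%; these are the second guides with 1 library. With an adjusted p below 0.05 by limma, the region at the start of GAS8 on chromosome 16 (90088810 to 90089154) was raised in 5 tables, with a mean log2 ratio of 3.28. That in an exon of RNF225 on chromosome 19 was raised in 4, all of second guides. A region at CITED4, which encodes a CBP-interacting coactivator, was raised in 3 of the same tables. Regions far from a start recurred as well. Those on chromosome 6 (148390 to 148945) and chromosome 9 (44992655 to 44993349) lay 142963 and 448541 bp from one. Each was raised in 3 tables, with means of 2.72 and 2.64. Both lists were looked at after the values were known. All tables share the 4 sgGal4 libraries, so raised regions are not independent between tables. The number of tables expected without any change was not worked out.

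High-ratio regions outside the cluster may be places where the guide pairs through the bases next to the protospacer-adjacent motif (PAM). In the 9 single-guide tables with at least 10 regions at a log2 ratio of 3 or more, a 20-base site next to NGG was chosen within the on-target region on every other high region, and the regions left out of that choice were then searched. A median of 59.0% of them, from 8.55% for sg3'HS1 to 83.9% for sgHS4, held an NGG preceded by at least 7 bases identical to the chosen site, against a median of 0.667% of regions with a log2 ratio under 0.5; Fisher's exact test, adjusted, was below 0.05 in 9 of 9 tables. The site chosen for another guide matched a median of 0% and at most 3.33% of the regions over 72 combinations. The amplified intervals around BCR and ABL1 held 0.271% of these regions, so they hold few of them. Copy number elsewhere in K562 was not examined. Whether open promoters contribute stays open, since the share near a transcription start differed by a median of 0.82 percentage points and by -22.4 to 22.8 across tables. Many of these regions, such as those near SYF2 and HIVEP2, carry no off-target tag in the authors' deposited tables.

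The promoter excess in the second-guide tables had a median of 36.3 percentage points over 7 tables. It was also 36.3 with the deep sgGal4 replicates 1 and 2 alone, which argues against the shallow sgGal4 libraries as the source of the median excess. For sgHS3-sg2 the excess was 5.63 points with all sgGal4 libraries and 21.3 with replicates 1 and 2 alone, so the choice of controls matters there. Raised regions near a start held a match of at least 7 bases more often than those under 0.5, by a median of 2.01 points over 7 tables. The match was to a site chosen within the on-target region on other raised regions near a start. The guide sequences themselves were not used. In the 5 tables with an excess above 30 points at most 4.92% of them held a match. This argues against pairing through 7 or more bases as the source of the excess there. Shorter matches were not counted, so pairing through fewer bases stays open. For sgHS2-sg2, with an excess of 1.51 points, the shares with a match were 9.21% and 0.667%, so pairing at some promoters is not excluded. The median GC content of the raised regions was between 69.7% and 72.7% in the 5 tables with an excess above 30 points, against 52.0% to 56.7% of the others, and within 5 bins of GC content the excess had a median of 8.18 points. GC content may therefore account for part of it. Neither bound set beforehand (below 5 or above 10 points) was reached by this median. In the 5 tables with an excess above 30 points the values were 6.73 and 8.18 for sgHBB-sg2 and sgHS4-sg2, 10.3 and 10.4 for sgHS1-sg2 and sgHBG-sg2, and higher still for sgHS5-sg2. They lie on both sides of 10, so GC content and promoters cannot be told apart. No biological explanation was tested.

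The pool libraries may not all have held the same guides. HS2 took 3.45%, 3.86%, 2.16% and 4.98% of the reads at the 5 targets in replicates 1 to 4, and 3058 of 9003 and 5342 of 13703 of these reads in replicates 5 and 6. Depth alone would leave the proportions equal, whereas Cramer's V over the 6 libraries was 0.199. The 11 regions raised by the single guide sgHS4 that the pool table lists held 0.237%, 0.240%, 0.191% and 0.166% of the reads in replicates 1 to 4, and 0.0342% and 0.0296% in replicates 5 and 6, no more than the 0.0306% to 0.0490% of the sgGal4 libraries, although replicates 5 and 6 had 1613 and 1594 reads at HS4 itself. The regions of other single guides differed the other way. Those of sgHS5 held 0.247%, 0.231%, 0.316% and 0.298% of the reads in replicates 1 to 4 and 1.94% and 2.85% in replicates 5 and 6, against 0.147% to 0.288% in sgGal4. Those of sgHS3 held 2.11%, 2.16%, 0.894% and 0.724%, and then 7.75% and 12.7%, against 0.215% to 0.429% in sgGal4. The sgHS4 values argue against that guide having been used in every pool library. In replicates 1 to 4 the share in the sgHS5 regions lay close to that of sgGal4, so the use of sgHS5 there is in doubt as well. A mixture that differed at more than 1 guide is a candidate explanation that the labels do not address.

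The sg3'HS1 libraries differed at their target (0.0433% and 4.38% of reads) but at the USP20 exon both were raised, where they held 1205 and 241 reads against at most 8 in an sgGal4 library.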
